A study of Mus musculus with 9 samples.

How the data were processed

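Poly(A) RNA of NP53 mouse diffuse midline glioma cells and of the TIM-3 knockout derivatives G1C7 and G2C9 was sequenced in 9 libraries, 3 per group, per the labels. The kit was stranded and reads were paired, 100 bp each, on a NovaSeq instrument, per the labels. The values are counts of reads per gene, which the authors made with featureCounts 1.6.0 on STAR alignments against GENCODE vM25 (GRCm38), per the file headers. Quality control with FastQC 0.11.8, alignment with STAR 2.6.1c and statistics with edgeR and limma are given in the submitters' processing notes; the authors' statistical results were not used here. In 9 of 9 file headers the options for pairs, strand, multi-mapping reads and reads in several genes were absent. Mates were thus counted separately, strand was ignored, and reads with several positions or in overlapping genes were dropped; between 74.1% and 75.6% of counts from 2 to 50 were even. Gene symbols and types came from a GENCODE vM21 reference, which held 55141 of the 55401 gene IDs; the other 260 kept their ID, and 3 symbols of the gene lists were not found. Aldoa has 2 IDs, so the glycolysis list has 19 tested members.

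CPM were computed from the deposited counts with TMM factors, which lay between 0.978 and 1.03. Mitochondrial genes held between 1.39% and 1.94% of reads. Genes were kept with filterByExpr (15659 of 55401). All 9 libraries entered one edgeR 4.0.16 quasi-likelihood fit with robust dispersion (R 4.3.3), with 6 residual degrees of freedom and a common biological coefficient of variation of 0.248. Each derivative and the mean of both were compared with Gcontrol, and G1C7 with G2C9. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE is the absolute log2 fold change over the square root of the F statistic.

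Gene lists were written by hand before the data were examined, as were the groups, the 4 comparisons, the tests, the naming rule and the alternatives except those said to be added later. Of 36 lists, 35 had 3 or more tested members; the list of T and NK cells did not and was not tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over 35 lists, and again with an estimated correlation, under which no list passed in any comparison (lowest adjusted p 0.236). Counts "adjusted over the list alone" adjust p-values within the list. The preset correlation treats list members as nearly independent, and both results stand beside each list called. The median and the mean of a list differed in sign in 7, 4, 9 and 4 of the 35 lists for G1C7, G2C9, the mean of both and G1C7 against G2C9.

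The naming rule covers the list of TIM-3 and its ligands. It also covers the 12 higher and 12 lower genes shared by both derivatives with the largest smaller change. Per pairwise comparison it takes the 8 higher and 8 lower genes with the largest change. Per list it takes up to 2 highest and 2 lowest called members, or 2 most abundant members where none was called. Shared genes and those with the largest change had to be protein coding, at a mean of 1 CPM or more and with no overlap of libraries. Names of the Gm and Rik kind were passed over (2 shared and 3 between the derivatives). Which of these genes the text names was chosen after their values were seen, and 2 of them are not reported here, though the counts below include them. Stability counts were therefore also made over all 425 results that the rule gives besides Havcr2: 336 were called, 184 of them in each of the 13 fits set beforehand for single genes (RLE, DESeq2, limma-voom, the block and each library left out) and 187 without each of the 9 libraries in turn. For the 195 results listed for the text the counts were 187, 124 and 126. Reading only genes with stable calls was tried and not used, since it would have raised that share.

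For genes at 0 reads in a group, folds are lower bounds against a floor of 6 reads over the group (3 read pairs). With 1 to 3 read pairs, the ratio of normalized reads is given with a 95% counting interval in read pairs. The correlation and covariance that shared controls give to the 2 comparisons were simulated 20 times with unchanged derivatives. At most 1 gene was called per comparison there, so the simulations say nothing on the number of shared calls.

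The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, which are not real results. With edgeR, 51 and 78 were recovered in G1C7 (11 of 140 calls false, 15293 genes), 41 and 76 in G2C9 (6 of 123, 15311 genes), 55 and 73 for the mean (8 of 136, 15314 genes), and 38 and 71 between the derivatives (4 of 113, 15327 genes). With DESeq2 1.42.0 (15659 genes), 68 and 83, 56 and 83, 69 and 83, and 55 and 79 were recovered, with 68 of 219, 52 of 191, 52 of 204 and 42 of 176 calls false. With limma-voom, 52 and 83, 38 and 77, 55 and 72, and 37 and 70 were recovered, with 12 of 147, 6 of 121, 9 of 136 and 5 of 112 false. A list of doubled genes called 0 other lists, and a chromosome shifted in simulation was found at 0.403.

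Alternatives were RLE and upper-quartile normalization, no filter, a stricter filter (1 CPM in 3 libraries), DESeq2, limma-voom, fits of the compared groups alone, the replicate number as a block, a 2-fold threshold, fry for the lists, and leaving out each library. Leaving out both libraries that stood apart, halved counts, limma-voom with quality weights, and offsets per chromosome or per 15 Mb window were added after the data were seen. Raw reads, alignments and the edited sequence of Havcr2 were not analysed here. No line cloned without an edit is given in the sources used here.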

Results

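Messenger RNA was sequenced from NP53 cells, a mouse line of diffuse midline glioma that serves as the control group Gcontrol, and from G1C7 and G2C9, derivatives of that line labelled as TIM-3 knockouts. TIM-3 is the product of Havcr2 and is best known as an inhibitory receptor of T cells. Each of the 3 groups had 3 libraries, and the series asks how loss of TIM-3 bears on tumour formation by this line. The G1C7 libraries held 54249228, 53231484 and 55743695 reads in genes, the G2C9 libraries 51469673, 50110129 and 50896035, and the Gcontrol libraries 53476717, 53569889 and 56035382. Both mates of a read pair were counted, so 6 reads over a group stand for 3 read pairs, the floor used here for a count of 0. In a library, 3 read pairs correspond to between 0.107 and 0.120 CPM (counts scaled to library size). Values below are CPM as mean ± SD with n = 3 libraries, or log2 fold changes ± SE from the edgeR fit. Intervals and floors cover counting error only. The labels do not say whether libraries came from separate cultures, so p-values measure only the spread between these libraries. Each call was tried again with each of the 9 libraries left out; where a call ended, the library named is the one that gave the highest adjusted p, and others can have ended it too.

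The Gcontrol libraries lay close together, and G1C7 replicate 2 and G2C9 replicate 3 stood apart from the other libraries of their groups. The first principal component, with 43.8% of the variance, placed the Gcontrol libraries at 68.4 to 69.1 and the 6 derivative libraries at -40.6 to -21.9. The second, with 24.8%, placed G1C7 replicate 2 at -79.4 and G2C9 replicate 3 at -49.8, with the other 7 libraries between 4.13 and 30.5. Within G1C7, the chi-square per degree of freedom between libraries was 4.40 for replicates 1 and 3, and 152 and 157 for the pairs with replicate 2. Within G2C9 it was 5.66 for replicates 1 and 2, and 98.4 and 93.9 for the pairs with replicate 3. Haptoglobin (Hp), an acute-phase protein, stood at 205 CPM in G1C7 replicate 2 and at 4.08 and 4.06 in the others of G1C7. It stood at 493 CPM in G2C9 replicate 3 and at 21.5 and 20.3 in the others of G2C9. No batch, culture or date in the labels sets these 2 libraries apart.

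**Figure D1:**
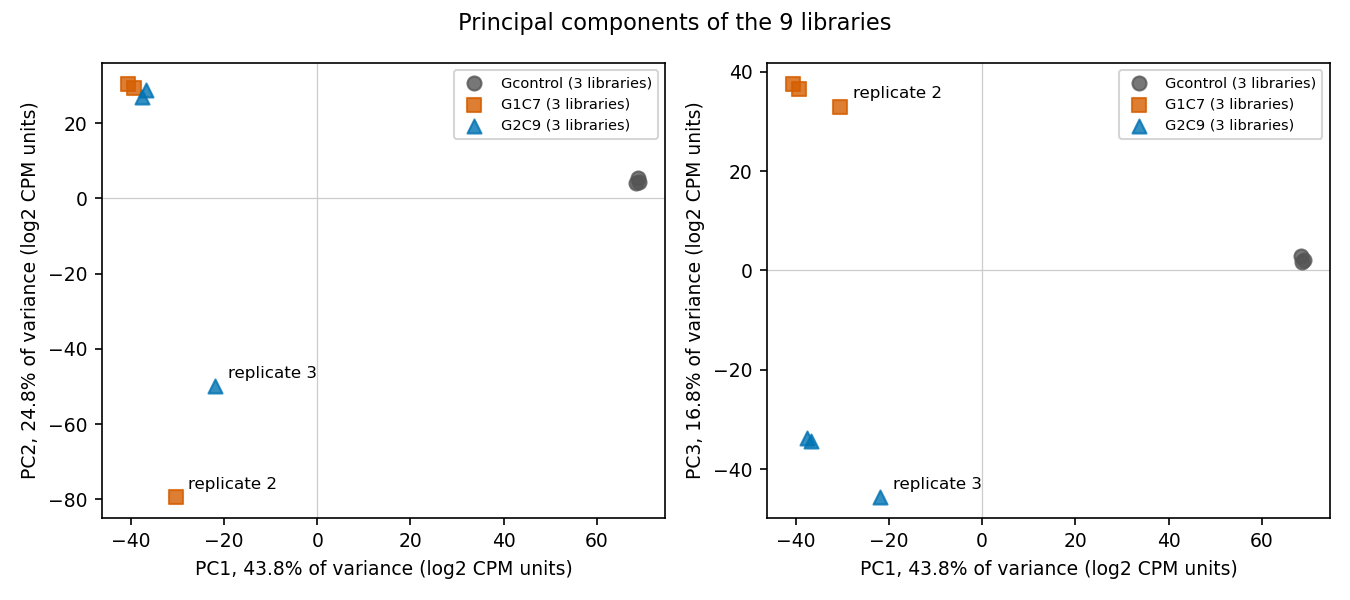
Principal components of log CPM, with the share of variance on each axis and a point for each of the 9 libraries, coloured by group. The first component (43.8%) parts Gcontrol from both derivatives, and the second (24.8%) parts G1C7 replicate 2 and G2C9 replicate 3 from the other 7 libraries.

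The transcript of the targeted gene was still read in both derivatives. Havcr2 (ENSMUSG00000020399.14, GRCm38 chromosome 11, 46454935 to 46481255, plus strand) had 74, 58 and 60 reads in the Gcontrol libraries, 55, 6 and 66 in G1C7, and 39, 30 and 28 in G2C9. Its level was 1.17 ± 0.175 CPM in Gcontrol, 0.781 ± 0.589 in G1C7 and 0.644 ± 0.116 in G2C9. The log2 fold change against Gcontrol was -0.58 ± 0.64 in G1C7 (adjusted p = 0.586) and -0.85 ± 0.64 in G2C9 (adjusted p = 0.448), and neither passed the test. For the mean of both derivatives it was -0.72 (adjusted p = 0.40), and G1C7 against G2C9 gave 0.28 (adjusted p = 0.916). G1C7 replicate 2, with 6 reads, weighed on these values: without it, the change was -0.06 in G1C7 (adjusted p = 0.899), -0.45 for the mean and 0.80 between the derivatives. Without it, Havcr2 passed the test in G2C9 at -0.85 (adjusted p = 0.0323), while the other libraries left out in turn gave adjusted p of up to 0.672. The change in G1C7 was -1.03 without G1C7 replicate 3, and the difference between the derivatives was then -0.18. That difference was 0.03 without G1C7 replicate 1, 0.43 without G2C9 replicate 1 and 0.17 without G2C9 replicate 3. The tested genes around Havcr2, on chromosome 11 at 45 to 60 Mb, had medians 0.22 and 0.38 below that of all genes in G1C7 and G2C9. Havcr2 was not tested apart from this shift. An edit that shifts the reading frame need not lower the transcript, and gene counts do not show the edited sequence. Galectin 9 (Lgals9), a ligand of TIM-3, stood at 17.6 ± 0.435 CPM in Gcontrol, 7.14 ± 3.69 in G1C7 (adjusted p = 0.135) and 4.97 ± 4.09 in G2C9 (adjusted p = 0.0604). Without G2C9 replicate 3, Lgals9 passed the test in G2C9, with a log2 fold change of -2.75 in place of -1.83 (adjusted p = 0.00486), and in G1C7 (-1.31, adjusted p = 0.0243). Without G1C7 replicate 2 it passed in G1C7 (-1.81, adjusted p = 0.0389) and in G2C9 (adjusted p = 0.0215). DESeq2 and limma-voom called it in both derivatives, and so did the fit without both libraries that stood apart. In the simulated counts, 68 of 219 DESeq2 calls in G1C7 and 52 of 191 in G2C9 were false, more than with edgeR. For the mean of both derivatives Lgals9 fell by 1.57 ± 0.44 on the log2 scale (adjusted p = 0.0380), a call kept in 2 of 9 fits with a library left out and with an adjusted p of 0.121 without Gcontrol replicate 3. Ceacam1, another ligand, stood at 0.0554 ± 0.0554 CPM in Gcontrol, 0.561 ± 0.464 in G1C7 (adjusted p = 0.0824) and 0.231 ± 0.118 in G2C9 (adjusted p = 0.314). By library it stood at 0.917, 0.0364 and 0.731 CPM in G1C7. It passed the test there without G1C7 replicate 2 (adjusted p = 0.00797) and with DESeq2 (0.0206), and without both libraries that stood apart in G1C7 (7.90e-05) and in G2C9 (0.0308). Bag6 was on the list of TIM-3 and its ligands, though it is not a ligand. It stood at 357 ± 16.5 CPM in Gcontrol, 433 ± 30 in G1C7 (adjusted p = 0.0596) and 367 ± 16.6 in G2C9 (adjusted p = 0.834). Bag6 passed the test in G1C7 with DESeq2 (0.0449), without G1C7 replicate 2 (0.0189), without G2C9 replicate 3 (0.0494) and without both. Its log2 fold change there was 0.28. The tested genes around it, on chromosome 17 at 30 to 45 Mb, had a median 0.41 above that of all genes in G1C7. Hmgb1 stood at 519 ± 14.7, 558 ± 119 and 577 ± 64.7 CPM (adjusted p = 0.700 in G1C7 and 0.593 in G2C9), and passed in both derivatives without both libraries that stood apart (2.05e-05 and 6.42e-05).

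In G1C7 against Gcontrol, 11 of 19 tested genes of cholesterol synthesis were higher, and 12 of 36 genes of the type I interferon response and 6 of 20 of the interferon gamma response were lower, with 1 of the latter higher. These 3 lists passed camera at its preset correlation and did not pass it with an estimated correlation (adjusted p of 0.767 to 0.795). Msmo1, a sterol oxidase of that pathway, rose from 76.5 ± 5.61 to 187 ± 21.7 CPM, and Fdft1, squalene synthase, from 77.9 ± 2.22 to 147 ± 3.32 CPM. The antiviral gene Rsad2 had 232 reads in Gcontrol and 2 in G1C7, a ratio of 115 (95% counting interval 20.2 to 4571). Oasl1 had 465 and 4, a ratio of 115 (31.4 to 953). The neighbours of Rsad2 on chromosome 12, Rnf144a, Cmpk2 and Sox11, fell from 278, 164 and 521 reads to 2, 2 and 0. The fall of Rsad2 thus need not be part of an interferon change. The log2 fold change of Oasl1 was -6.72, and -10.22 without G1C7 replicate 2, a fitted value that depends on the prior count. Cspg4, which encodes the NG2 proteoglycan of oligodendrocyte precursors, fell from 43.6 ± 4.72 to 1.30 ± 0.341 CPM. Fos, an immediate early transcription factor, fell from 131 ± 3.11 to 32.4 ± 7.13 CPM.

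Of 15659 genes tested with edgeR, 2740 changed in G1C7 at an adjusted p under 0.05, with 1373 higher and 1367 lower. Of these, 988 changed at least 2-fold, 293 higher and 695 lower. In each of the 2740, the 3 G1C7 libraries lay on one side of the 3 Gcontrol libraries; over all genes tested this held for 43.0%, where chance gives 10%. The largest higher changes that the naming rule gave here included Gria1, an AMPA-type glutamate receptor subunit (log2 fold change 3.70 ± 0.46, adjusted p = 0.00141), Entpd1, which hydrolyses extracellular ATP (4.04 ± 0.91, 0.0172), Dscam, a neuronal adhesion molecule (3.56 ± 0.85, 0.0220), and Car6, a carbonic anhydrase (3.18 ± 0.86, 0.0360). Without G1C7 replicate 2, Entpd1 stood at 2.41 and Car6 at 1.45. The calls of Entpd1, Dscam and Car6 ended without 1 or more of the other libraries, at adjusted p of up to 0.0776 without Gcontrol replicate 1, 0.0907 without Gcontrol replicate 3 and 0.133 without Gcontrol replicate 2, respectively. Among the lower ones, Cap2, a regulator of actin, Rragb, a GTPase of the amino acid pathway to mTORC1, and Atp8a1, a phospholipid flippase, had 0 reads in the 3 G1C7 libraries. Against the floor they were at least 465-fold, 274-fold and 107-fold lower. The count of 2740 was 1808 without G1C7 replicate 1 and 4133 without G1C7 replicate 2, and 1181, 1296 and 1279 without Gcontrol replicates 1, 2 and 3. Without both libraries that stood apart it was 8581, among them 2730 of the 2740.

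By gene list in G1C7, 11 of 19 tested cholesterol genes rose and none fell (16 and 0 adjusted over the list alone), with a median log2 fold change of 0.70. The camera test gave an adjusted p of 1.07e-09, and adjusted p = 0.767 with an estimated correlation. Of 36 genes of the type I interferon response, 12 fell and none rose (17 lower and 1 higher adjusted over the list alone), with a median of -1.81 (adjusted p = 5.01e-08 by camera; adjusted p = 0.767 with an estimated correlation). Of 20 genes of the interferon gamma response, 6 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.82 (adjusted p = 3.45e-04 by camera; adjusted p = 0.795 with an estimated correlation). Gbp3, a guanylate-binding protein, fell by 2.66 ± 0.23 and Gbp5 fell by 3.84 ± 0.87 on the log2 scale, and Ifngr1, the interferon gamma receptor chain, was the member that rose (0.43 ± 0.08). The call of Gbp5 ended without Gcontrol replicate 1 (adjusted p = 0.0857) and that of Ifngr1 without the same library (0.0563). These 3 lists moved with the library that stood apart. Against Gcontrol, the median of the type I list was -2.82 and -2.21 in G1C7 replicates 1 and 3 and -0.87 in replicate 2, that of the interferon gamma list -1.79, -1.62 and -0.09, and that of the cholesterol list 0.78, 0.76 and 0.36. Among growth factors and their receptors, 4 of 22 rose and none fell (6 and 0 adjusted over the list alone), with a median of 0.37 (adjusted p = 0.0448 by camera; adjusted p = 0.767 with an estimated correlation). Its members Igf1 and Igf1r, insulin-like growth factor 1 and its receptor, rose by 2.64 ± 0.41 and 0.68 ± 0.15. Igf1r lost its call without Gcontrol replicate 2 (adjusted p = 0.0722), and the list lost its own without G1C7 replicate 2 or Gcontrol replicate 1 (adjusted p of up to 0.105). Among WNT targets and regulators, 5 of 13 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.34. There camera gave adjusted p = 0.0448, and adjusted p = 0.767 with an estimated correlation; the call was kept in 1 of 9 fits with a library left out, with an adjusted p of up to 0.202. By library the WNT median was 0.20, 0.72 and 0.06, highest in the library that stood apart. Apcdd1, an inhibitor of WNT signalling, rose by 1.45 ± 0.16. These 5 lists were the ones called among 35; 3 were called without Gcontrol replicate 1 and 8 without G1C7 replicate 2.

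In G2C9 against Gcontrol, 11 of 36 type I interferon genes, 6 of 20 interferon gamma response genes and 7 of 20 genes of MHC class I antigen presentation were lower, with 2, 0 and 2 higher. Of 7 Hox genes 4 were higher and 1 lower, and the matrix metalloproteinase Mmp3 was higher. These 4 lists passed camera at its preset correlation and did not pass it with an estimated correlation (adjusted p of 0.408 to 0.781), and the class I list lost its call without G2C9 replicate 1 or 2 (adjusted p of up to 0.0904). Mmp3 (ENSMUSG00000043613.8, chromosome 9, 7445822 to 7455975) rose from 51.1 ± 0.910 to 625 ± 359 CPM, a log2 fold change of 3.61 ± 0.37 (adjusted p = 7.11e-04). Hoxa7, a transcription factor of body patterning, rose from 8.84 ± 0.264 to 28.1 ± 0.672 CPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 7078, 4607, 2951 and 2036 reads in Gcontrol and 0 in the 3 G2C9 libraries. Notch1, a receptor of the NOTCH pathway, fell from 4.40 ± 0.193 to 0.824 ± 0.407 CPM, and Adam8, a membrane metalloproteinase, from 13.6 ± 1.10 to 2.06 ± 0.381 CPM.

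In all, 2109 genes changed in G2C9, with 979 higher and 1130 lower, and 841 of them at least 2-fold (223 higher, 618 lower). Each of the 2109 had its 3 G2C9 libraries on one side of the 3 Gcontrol libraries, a share of 43.3% over all genes tested where chance gives 10%. Ddx3y, Eif2s3y, Kdm5d and Uty were at least 1078-fold, 702-fold, 449-fold and 310-fold lower. Besides Mmp3, the largest higher changes that the rule gave included Col25a1, a membrane collagen (3.94 ± 0.85, adjusted p = 0.0173). Its call ended without Gcontrol replicate 1 (adjusted p = 0.0868). The count of 2109 was 4113 without G1C7 replicate 2, whose spread enters the shared fit, 1185 and 1175 without G2C9 replicates 1 and 2, and 878, 1022 and 938 without Gcontrol replicates 1, 2 and 3. Without both libraries that stood apart it was 8383, among them 2108 of the 2109.

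By gene list in G2C9, 11 of 36 type I interferon genes fell and 2 rose (11 and 2 adjusted over the list alone), with a median log2 fold change of -1.12 (adjusted p = 2.37e-06 by camera; adjusted p = 0.718 with an estimated correlation). Rsad2 had 0 reads and was at least 35.3-fold lower, and Slfn5 had 181 reads in Gcontrol and 2 in G2C9, a ratio of 82.7 (14.4 to 3284). Rnf144a, Cmpk2 and Sox11, neighbours of Rsad2, had 0, 2 and 0 reads in G2C9, so its fall need not be part of an interferon change. The members that rose were Slfn8 (1.84 ± 0.50) and Ifit2 (0.60 ± 0.15). Of 20 interferon gamma response genes, 6 fell and none rose (8 and 1 adjusted over the list alone), with a median of -0.88 (adjusted p = 1.99e-04 by camera; adjusted p = 0.697 with an estimated correlation). Gbp3 fell by 2.17 ± 0.22. Of 20 genes of MHC class I antigen presentation, 7 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -0.48 (adjusted p = 0.0300 by camera; adjusted p = 0.781 with an estimated correlation). Psmb9 and Psmb8, subunits of the immunoproteasome, fell, Psmb8 from 3.29 ± 0.0792 to 0.177 ± 0.236 CPM, while H2-T22 (1.61 ± 0.40) and Pdia3 (0.55 ± 0.14) rose. H2-T22 stood at 1.00 without G2C9 replicate 3. Calls ended for Slfn8 without Gcontrol replicate 2 (adjusted p = 0.161), Ifit2, H2-T22 and Pdia3 without Gcontrol replicate 3 (0.132, 0.115 and 0.122), Psmb9 without G2C9 replicate 2 (0.104) and Psmb8 without G2C9 replicate 1 (0.121). The class I list itself lost its call without G2C9 replicate 1 or 2 (adjusted p of up to 0.0904). The median of the type I interferon list against Gcontrol was -2.23 and -1.95 in G2C9 replicates 1 and 2, and -0.29 in replicate 3, that of the interferon gamma list -1.46, -1.46 and -0.20, and that of the class I list -0.59, -0.57 and -0.25.

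Cholesterol genes were also higher in G2C9, with 4 of 19 up and none down (7 and 0 adjusted over the list alone) and a median of 0.26 (adjusted p = 0.00558 by camera; adjusted p = 0.800 with an estimated correlation). By library the list median was 0.40, 0.44 and 0.14, lowest in the library that stood apart. Msmo1 rose by 0.74 ± 0.13 and Sc5d, a sterol desaturase, by 0.61 ± 0.10. Of 7 tested Hox genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.60 (adjusted p = 0.0139 by camera; adjusted p = 0.408 with an estimated correlation). Hoxa7 rose by 1.67 ± 0.13 and Hoxa5 by 1.13 ± 0.18; Hoxa10, with 48 reads in Gcontrol and 4 in G2C9 (ratio 10.97, 2.72 to 95.7), was the one that fell, and its call ended without Gcontrol replicate 1 (adjusted p = 0.120). Growth factors and their receptors had 4 of 22 higher and none lower (8 and 2 adjusted over the list alone), with a median of 0.39 (adjusted p = 0.0139 by camera; adjusted p = 0.697 with an estimated correlation). Of 18 immediate early and heat shock genes, 4 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.0300 by camera; adjusted p = 0.408 with an estimated correlation). Fos fell by 1.85 ± 0.16 and the heat shock gene Hspa1a by 3.27 ± 0.51, and Jun rose by 0.60 ± 0.13, a call that ended without Gcontrol replicate 2 (adjusted p = 0.0759). Of 30 matrix proteases and integrins, 7 fell and 4 rose (11 and 5 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.0415 by camera; adjusted p = 0.697 with an estimated correlation). Adam8 fell by 2.72 ± 0.21 and Mmp9, a gelatinase, by 3.60 ± 0.30. Of 12 neural stem and progenitor markers, 3 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.15 (adjusted p = 0.0441 by camera; adjusted p = 0.408 with an estimated correlation). Igf2bp3, an RNA-binding protein, fell by 2.99 ± 0.35, and Lhx2, a homeobox gene, rose by 1.05 ± 0.13. Of 19 NF-kB targets, 4 fell and none rose (4 and 0 adjusted over the list alone), with a median of -0.16 (adjusted p = 0.0490 by camera; adjusted p = 0.781 with an estimated correlation). Nfkbia, the inhibitor of NF-kB, fell by 0.87 ± 0.12. In G2C9 replicates 1, 2 and 3, the NF-kB median was -0.28, -0.34 and 0.01 and that of the proteases and integrins -0.38, -0.41 and -0.03, near Gcontrol in the library that stood apart, while that of immediate early and heat shock genes was -0.11, -0.19 and -0.51, lowest there. The protease and stem cell lists lost their calls without G2C9 replicate 1 or 2 (adjusted p of up to 0.132 and 0.0774). The NF-kB list lost its own without any of G1C7 replicates 1 to 3 or G2C9 replicates 1 and 2 (up to 0.127). These 10 lists were the ones called among 35, and 6 were called without either G2C9 replicate 1 or 2.

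The derivatives shared many changes. Slc14a1, a urea transporter (ENSMUSG00000059336.14, chromosome 18, 78100091 to 78142119), rose from 0.754 ± 0.207 CPM in Gcontrol to 51.7 ± 20.0 in G1C7 and 31.0 ± 1.00 in G2C9. Serpine2, an inhibitor of serine proteases (ENSMUSG00000026249.10, chromosome 1, 79794197 to 79861180), had 16324 reads in Gcontrol and 2 in each derivative, a ratio of 8073 in G1C7 (1449 to 318918) and 7459 in G2C9 (1338 to 294632). Pcdh7, a protocadherin (ENSMUSG00000029108.14, chromosome 5, 57717967 to 58133230), stood at 67.6 ± 0.618 CPM in Gcontrol and at 0.0365 ± 0.0365 and 0.161 ± 0.139 in the derivatives.

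In both derivatives 1432 genes changed in the same direction, 714 higher and 718 lower, and 15 in opposite directions. These were 52.3% of the G1C7 calls and 67.9% of the G2C9 calls. Independent lists of these sizes would share 85.8 higher and 98.6 lower genes. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.749, where 20 simulations of unchanged derivatives set against the same controls gave a median of 0.496. The covariance was 0.893, where the simulations gave a median of 0.0733. The simulations drew each library independently. In the data, the deviations of G1C7 replicate 2 and G2C9 replicate 3 from their groups correlated at 0.677, which can raise both values. The excess over the simulations is thus not a measure of shared changes alone. The same 3 Gcontrol libraries serve both comparisons and are too few to be divided between them. The count of 1432 was 2478 without G1C7 replicate 2, 848 and 840 without G2C9 replicates 1 and 2, and 558, 630 and 600 without Gcontrol replicates 1, 2 and 3. Without both libraries that stood apart it was 6070, among them 1429 of the 1432.

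Besides Slc14a1, genes that rose in both derivatives included Unc13c, a synaptic vesicle protein, Itpkb, an inositol trisphosphate kinase, and Igf1. Others were the scavenger receptor Cd163, the calpain family member Capn6 and the growth factor Bmp3. Unc13c rose by 4.11 ± 0.43 in G1C7 and 2.92 ± 0.41 in G2C9, Itpkb by 2.78 ± 0.25 and 3.58 ± 0.26, and Cd163 by 2.52 ± 0.32 and 2.86 ± 0.32. Igf1 rose by 2.64 ± 0.41 and 2.61 ± 0.41, Capn6 by 2.50 ± 0.41 and 3.06 ± 0.42, and Bmp3 by 2.47 ± 0.44 and 2.50 ± 0.44. Lrrc36 had 2 reads in Gcontrol and 438 and 435 in the derivatives, ratios of 221 (39.3 to 8784) and 238 (42.4 to 9465). The cytokines Ptn (2.65 ± 0.67 and 4.20 ± 0.71) and Tslp (2.44 ± 0.53 and 2.59 ± 0.53), and Fam198b (2.76 ± 0.75 and 3.96 ± 0.79) and Pgpep1l (3.71 ± 0.63 and 2.90 ± 0.62), rose as well. Their calls were less stable. Without G1C7 replicate 2, Fam198b stood at 1.25 and Tslp at 1.63 in G1C7. In G1C7, adjusted p reached 0.107 for Ptn without Gcontrol replicate 2, 0.0727 for Tslp without Gcontrol replicate 1 and 0.134 for Fam198b without Gcontrol replicate 3. In G2C9 it reached 0.0733 for Tslp without Gcontrol replicate 1, 0.0667 for Fam198b without Gcontrol replicate 3 and 0.0767 for Pgpep1l without Gcontrol replicate 2.

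Among the shared falls, the neural transcription factor Sox11, the adhesion molecule Igsf9b, and Ptgr2, Elmod1 and Zcchc3 had 0 reads in both derivatives. They were at least 85.9-fold, 200-fold, 216-fold, 83.9-fold and 82.8-fold lower in G1C7, and at least 79.3-fold, 185-fold, 199-fold, 77.5-fold and 76.5-fold lower in G2C9. Nsg1, Jaml and the transcription factor Sall1 had 2 reads each in G1C7, ratios of 996 (178 to 39342), 435 (77.7 to 17229) and 295 (52.5 to 11681), and 0 in G2C9, at least 307-fold, 134-fold and 90.8-fold lower. Adamts2, a procollagen protease, fell from 11.8 ± 0.673 CPM to 0.0486 ± 0.0841 and 0.0524 ± 0.0454; its log2 fold change in G1C7 was -7.84, and -12.28 without G1C7 replicate 2, a fitted value that depends on the prior count, since the other libraries of G1C7 had 0 reads. Cspg4 fell by 5.06 ± 0.26 and 3.35 ± 0.24 on the log2 scale, while Nkx2-2, another gene of oligodendrocyte precursors, rose by 1.19 ± 0.15 and 1.09 ± 0.15. Fos fell by 2.01 ± 0.16 and 1.85 ± 0.16, Hspa1a by 3.44 ± 0.51 and 3.27 ± 0.51, and Id3, a target of BMP signalling, by 1.08 ± 0.13 and 1.02 ± 0.13. Exons of Hmgb1, Itpkb, Capn6, Fam198b, Ptgr2, Nsg1, Pcdh7, Jaml, Nkx2-2 and Hspa1a overlap those of another annotated gene. The same holds for Cap2, Atp8a1, Dscam, Oasl1, Fdft1, Slfn5, Psmb8, Psmb9, H2-T22 and Pdia3. It holds as well for Hoxa7, Jun, Adam8, Igf2bp3, Notch1, Notch2 and Ltbp2. Counting took no account of strand and dropped reads in overlaps, so these counts can hold reads of the neighbour or miss their own.

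**Figure D2:**
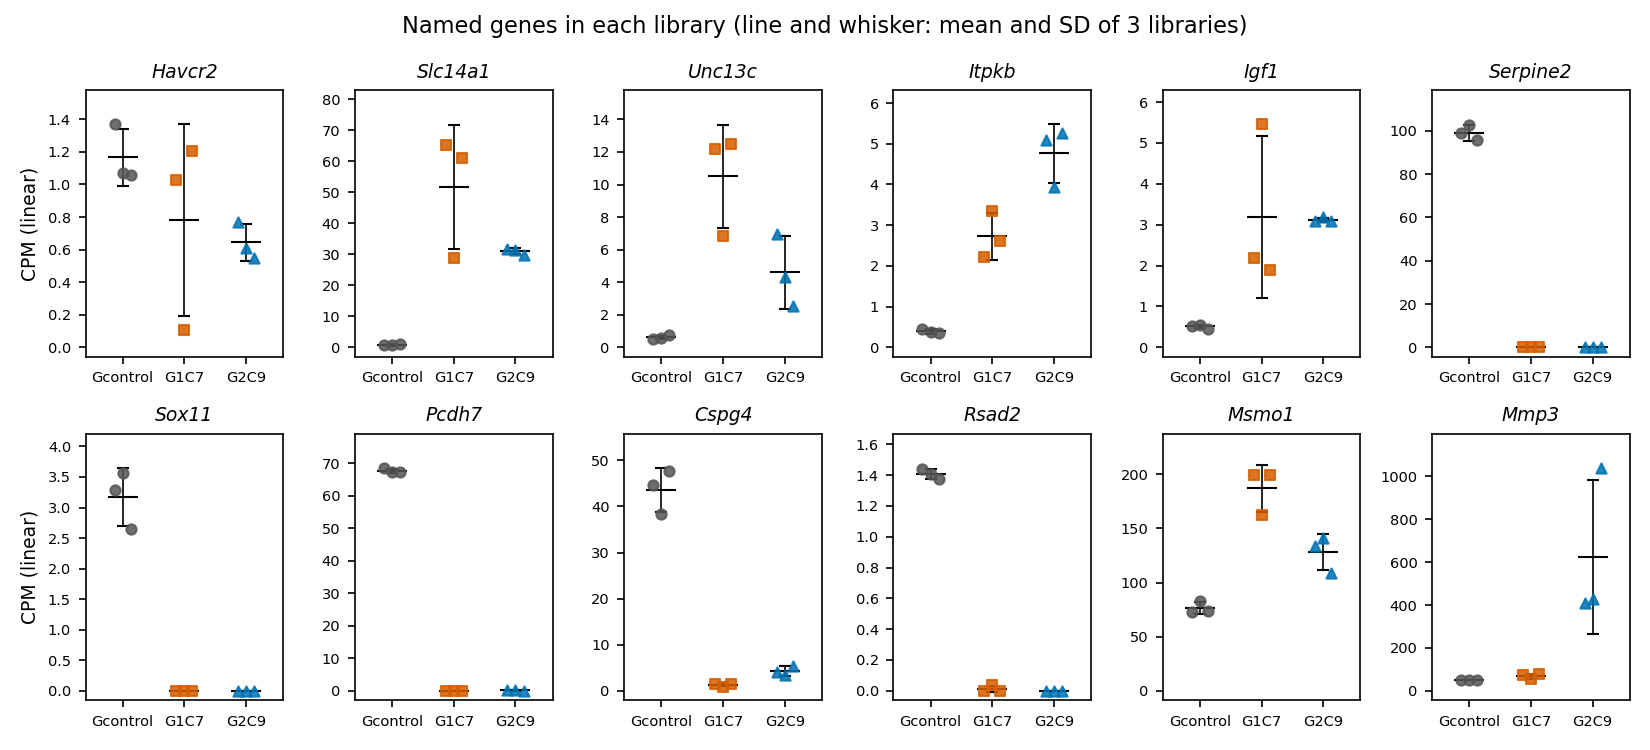
CPM of 12 genes in each of the 9 libraries on linear axes that include 0, with points for libraries and the mean and SD of each group. Slc14a1 lay between 28.7 and 65.3 CPM in the 6 derivative libraries and at or below 0.988 in Gcontrol.

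With the mean of both derivatives set against Gcontrol, 3124 genes changed, 1460 higher and 1664 lower, and 1035 of them at least 2-fold (252 higher, 783 lower). In 2818 of the 3124 the 6 derivative libraries lay on one side of the 3 Gcontrol libraries. Type I interferon genes had 13 of 36 lower and 1 higher (16 and 1 adjusted over the list alone), with a median of -1.56 (adjusted p = 2.17e-08 by camera; adjusted p = 0.554 with an estimated correlation). Interferon gamma response genes had 7 of 20 lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 4.80e-05 by camera; adjusted p = 0.554 with an estimated correlation). Cholesterol genes had 10 of 19 higher and none lower (12 and 0 adjusted over the list alone), with a median of 0.48 (adjusted p = 1.69e-06 by camera; adjusted p = 0.554 with an estimated correlation). Growth factors and receptors had 5 of 22 higher and none lower (6 and 0 adjusted over the list alone; adjusted p = 0.0210 by camera; adjusted p = 0.554 with an estimated correlation). Matrix proteases and integrins had 8 of 30 lower and 2 higher (8 and 4 adjusted over the list alone; adjusted p = 0.0402 by camera; adjusted p = 0.554 with an estimated correlation). The protease list kept its call in 5 of 9 fits with a library left out, with an adjusted p of up to 0.0831, and ended without G2C9 replicate 1, 2 or 3 or Gcontrol replicate 3. The count of 3124 was 4986 without G1C7 replicate 2 and 1318, 1551 and 1455 without Gcontrol replicates 1, 2 and 3. It was 9252 without both libraries that stood apart, among them 3120 of the 3124. The 5 lists were 8 without G1C7 replicate 2.

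**Figure D3:**
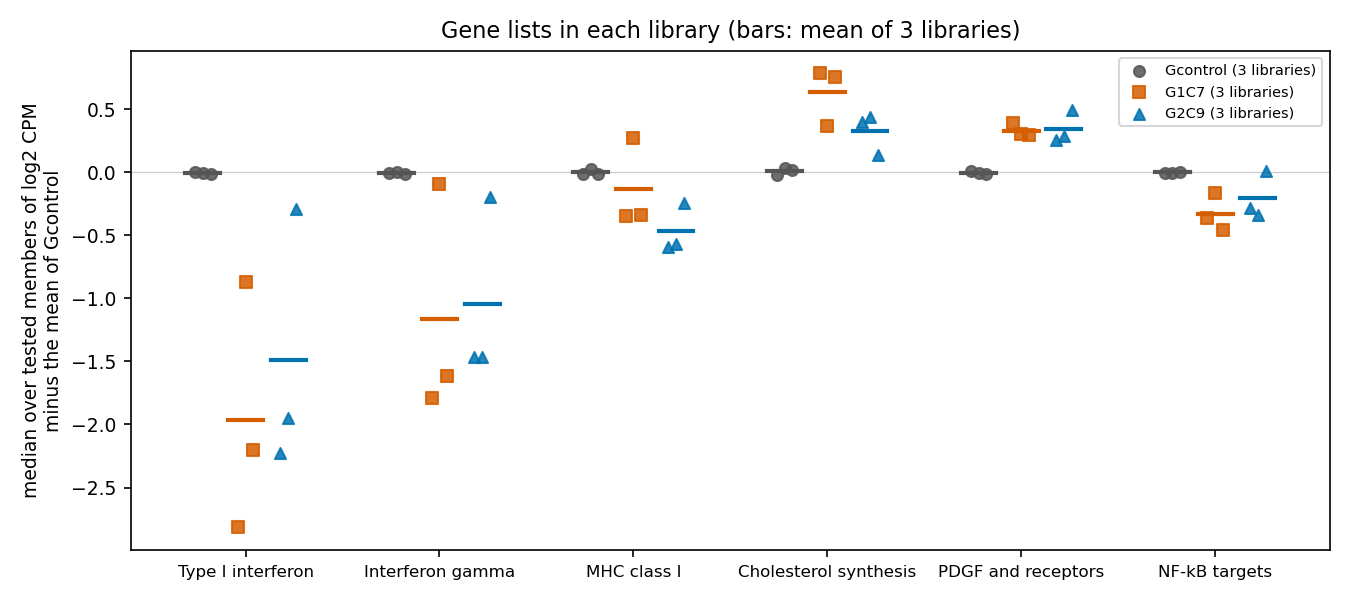
Median log2 level of 6 gene lists in each library against the mean of Gcontrol, with a point for each of the 9 libraries. The type I interferon list lay at -2.82, -0.87 and -2.21 in G1C7 and at -2.23, -1.95 and -0.29 in G2C9, nearest to Gcontrol in the 2 libraries that stood apart.

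Set against each other, the derivatives differed in genes that were silent in one and read in the other. Rragb, Gata4, a transcription factor of heart and gut development, and Atp8a1 had 0 reads in G1C7 and 1281, 973 and 489 in G2C9, at least 231-fold, 176-fold and 88.2-fold lower. Ddx3y, Eif2s3y, Kdm5d and Uty had 3733, 3604, 1742 and 1335 reads in G1C7 and 0 in G2C9. Mmp3 stood at 67.6 ± 12.2 CPM in G1C7 and 625 ± 359 in G2C9, a log2 fold change of -3.21 ± 0.36 (adjusted p = 0.00264). Notch1 was higher in G1C7 by 2.23 ± 0.32 (adjusted p = 0.00782), and Nes, an intermediate filament of neural progenitors, by 0.67 ± 0.08 (adjusted p = 0.00450). The test called 526 genes, 268 higher and 258 lower in G1C7, and 241 of them at least 2-fold. The spread in this test came from all 9 libraries, so the Gcontrol libraries, which lay close together, also set it. A fit of the derivative libraries alone called fewer genes, as given in the section on processing. In each of the 526, the libraries of the derivatives did not overlap, a share of 18.2% over all genes where chance gives 10%. Of the 1432 shared changes, 91 also differed in size between the derivatives. The count of 526 was 1286 without G1C7 replicate 2, and 230, 236, 227 and 186 without G1C7 replicates 1 and 3 and G2C9 replicates 1 and 2. It was 254, 284 and 275 without Gcontrol replicates 1, 2 and 3, and 4320 without both libraries that stood apart, among them the 526.

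Cholesterol genes were higher in G1C7 than in G2C9, with 3 of 19 called higher and none lower (8 and 0 adjusted over the list alone) and a median of 0.36 (adjusted p = 1.48e-06 by camera; adjusted p = 0.901 with an estimated correlation). Fdft1 differed by 0.44 ± 0.07, a call that ended without G2C9 replicate 1 (adjusted p = 0.0790). Hox genes were lower, with 1 of 7 called (3 adjusted over the list alone) and a median of -0.52 (adjusted p = 7.52e-04 by camera; adjusted p = 0.236 with an estimated correlation); that gene was Hoxa7, at -1.16 ± 0.13. Of 33 chemokines and cytokines, 5 were lower and none higher (5 and 0 adjusted over the list alone), with a median of -0.35 (adjusted p = 0.00774 by camera; adjusted p = 0.935 with an estimated correlation). Against Gcontrol this list lay at -0.99, 0.43 and -1.02 in G1C7 and at -0.08, -0.23 and 0.78 in G2C9, so that G1C7 replicate 2 lay above G2C9 replicates 1 and 2. Among its members were Csf3 (-2.09 ± 0.40) and Lif (-1.56 ± 0.33), which stood at -1.36 and -0.97 without G2C9 replicate 3. Their calls ended without G1C7 replicate 1 (adjusted p = 0.107, Csf3) and G1C7 replicate 3 (0.129, Lif), and that of the list without G1C7 replicate 3 or G2C9 replicate 3 (up to 0.379). MHC class I genes had none called (1 higher and 0 lower adjusted over the list alone) and a median of 0.51. The camera test gave adjusted p = 0.0140, and adjusted p = 0.914 with an estimated correlation. This call ended without G1C7 replicate 2 or G2C9 replicate 1 or 2 (up to 0.180). Against Gcontrol this list lay at -0.34, 0.27 and -0.34 in G1C7 and at -0.59, -0.57 and -0.25 in G2C9. G2C9 replicate 3 thus lay above G1C7 replicates 1 and 3. The H2 genes of the list lie on chromosome 17. There, all tested genes at 30 to 45 Mb lay at 0.41 in G1C7 and 0.05 in G2C9. The list was not tested apart from this shift. Of 11 NOTCH genes, Notch1 was higher and Notch2 lower (4 and 1 adjusted over the list alone), with a median of 0.66 (adjusted p = 0.0434 by camera; adjusted p = 0.792 with an estimated correlation). The NOTCH list lost its call without G1C7 replicate 2 or G2C9 replicate 2 (up to 0.203), and Notch2 its own without G1C7 replicate 1 (adjusted p = 0.0964). Notch2 lies on chromosome 3, where the tested genes at 90 to 105 Mb had a median 0.46 below that of all genes in G1C7. It stood at 247 CPM in Gcontrol, 168 in G1C7 and 262 in G2C9, and was not tested apart from this shift. Of 6 oligodendrocyte precursor markers, Cspg4 was lower by test at -1.71 ± 0.24 (3 lower and 0 higher adjusted over the list alone). The list median was -0.48, with adjusted p = 0.0173 by camera and adjusted p = 0.369 with an estimated correlation. This call ended without G1C7 replicate 3 (0.0652) and without both libraries that stood apart (0.0929). Against Gcontrol the list lay at 0.40, 0.05 and 0.14 in G1C7 and at 0.45, 0.57 and -0.12 in G2C9. G2C9 replicate 3 thus lay below each G1C7 library. Only these 6 of 15 listed markers passed the filter, and Olig1, Olig2 and Ptprz1 had 0 reads. Of 7 macrophage and microglia markers none was called, also adjusted over the list alone (0 and 0), with a median of -0.67 (adjusted p = 0.0434 by camera; adjusted p = 0.914 with an estimated correlation); the call ended without G1C7 replicate 1 or 3 or G2C9 replicate 3 (up to 0.351). Against Gcontrol this list lay at -1.05, 0.12 and -0.97 in G1C7 and at -0.23, -0.20 and 1.40 in G2C9. The type I interferon list did not pass the test between the derivatives (median -0.17, adjusted p = 0.483 by camera; adjusted p = 0.935 with an estimated correlation).

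Changes were not spread evenly over the genome. In G1C7 the median log2 fold change of the 778 tested genes on chromosome 17 lay 0.40 above that of all genes, with 78.4% of them on that side. Chromosome 3 lay at -0.35 (839 genes, 74.0% on that side), with the genes of its first 75 Mb at -0.01 and the rest at -0.47, and chromosome 10 at 0.27 (771 genes, 76.3%). In G2C9 chromosome 11, which holds Havcr2, lay at -0.30 (1232 genes, 79.0%) and chromosome 10 at 0.26 (771 genes, 77.4%). Chromosome 11 lay at -0.22 in G1C7. Chromosomes 3 and 17 differed between the derivatives, at -0.26 and 0.27 for G1C7 against G2C9.

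**Figure D4:**
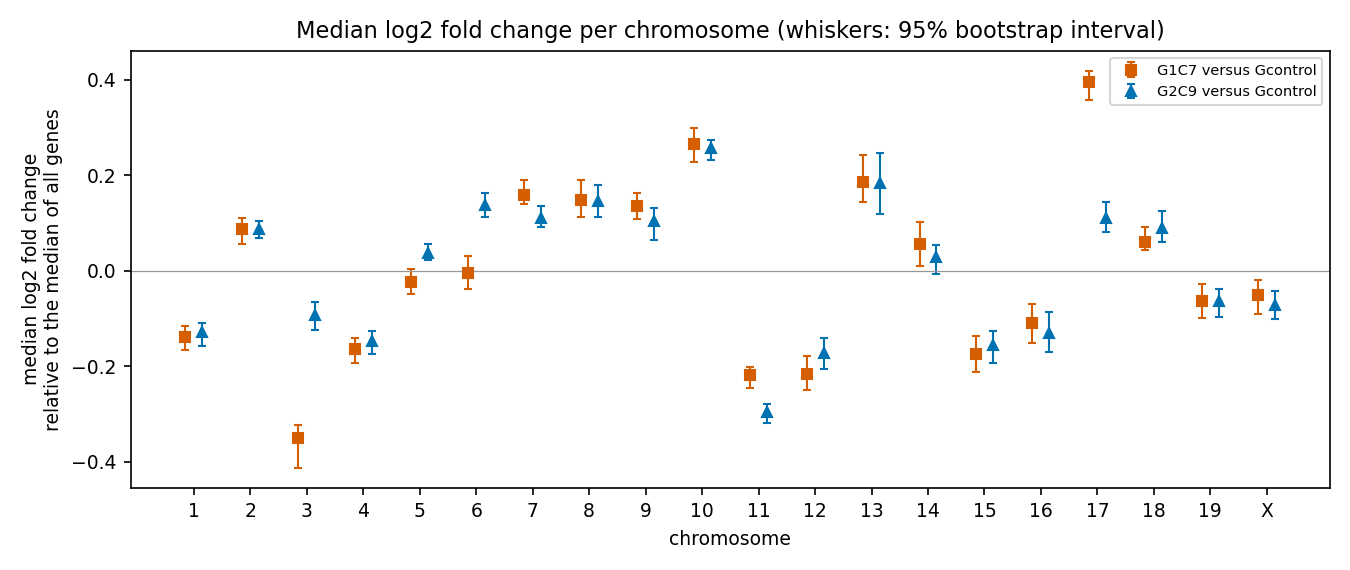
Median log2 fold change of the tested genes of each chromosome against that of all genes, for each derivative against Gcontrol, with 95% bootstrap intervals over genes. Chromosome 17 lay at 0.40 in G1C7 and 0.11 in G2C9, and chromosome 11 at -0.22 and -0.30.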

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

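The tests for swapped labels, for Gcontrol RNA, for window shifts, for the whole of chromosome 3 and for descent from differing cells were chosen after the result was seen. Of 53 genes named by size or role, 19 differed between the derivatives in edgeR's test of that difference, which is why they are listed here. The 53 include the 8 higher and 8 lower genes that the naming rule took from the calls of this same comparison. Those differ by construction, so 19 of 53 does not measure how often genes differ. In each of the 19, the 3 libraries of one derivative lay on one side of the 3 of the other. The same held for each of the 526 genes called.

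Of genes lower in G1C7, Rragb, Gata4, Atp8a1, Ildr2, Soga3, Slc4a3, Ehd3, Dusp22 and Cap2 had 0 reads there. They were at least 231-fold, 176-fold, 88.2-fold, 68.4-fold, 57.4-fold, 36.6-fold, 15.9-fold, 12.6-fold and 11.4-fold lower than in G2C9. Mmp3 was lower in G1C7 as well, at -3.21 ± 0.36 on the log2 scale. Of genes lower in G2C9, Ddx3y, Eif2s3y, Kdm5d, Uty and Zfp518b had 0 reads there, at least 575-fold, 555-fold, 268-fold, 206-fold and 29.3-fold lower than in G1C7. Zfp521 had 2 reads, a ratio of 392 (69.9 to 15508), and Eid2 had 4, a ratio of 50.3 (13.6 to 421). Tspan6 differed by 5.91 ± 0.78 and Gria1 by 3.23 ± 0.45; without G2C9 replicate 3, Tspan6 stood at 10.78, a fitted value that depends on the prior count, since the other libraries of G2C9 had 0 reads.

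Medians of chromosomes were shifted in the derivatives. Over both, 5 chromosome medians lay 0.25 or more from that of all genes with 70% of genes on that side. All 5 were left after correction for GC content and length, and the 5 were there without the 2 libraries that stood apart, which argues against these as the whole cause. For chromosome 3 in G1C7, a change of the whole chromosome is argued against by its 11 windows of 15 Mb. Their medians in order were 0.06, 0.08, -0.02, -0.05 and -0.04, then -0.44, -0.46, -0.49, -0.48, -0.49 and -0.46. The 229 genes of the first 5 windows had a median of -0.00704 (95% bootstrap interval -0.06 to 0.06). The 610 genes of the other 6 had -0.47 (-0.49 to -0.43). The first 5 were picked for lying within 0.1 of the median of all genes, so their joint median near it was fixed by that choice. In the other 4 cases, chromosomes 10 and 17 in G1C7 and 10 and 11 in G2C9, each window lay on the side of its chromosome, which is consistent with gain or loss of whole chromosomes, and this may be present in part of the cells. Chromosome 13, not among the 5, ran from -0.40 at 0 to 15 Mb to 0.45 at 90 to 105 Mb and -0.06 at 105 to 120 Mb in G1C7, and from -0.45 to 0.51 and -0.08 in G2C9. Changes of segments stay open; DNA was not measured.

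G1C7 replicate 2 and G2C9 replicate 3 lay apart from the other libraries of their groups. Swapped derivative labels are argued against by 0% of 7 and 6 on and off genes on the wrong side in these libraries. RNA of Gcontrol cells is argued against by a median of 0% of the Gcontrol level over 7 genes off in the other derivative libraries (highest 1.24% and 0.663%). GC content and length took 1.05% and 3.44% of the variance of the deviations, which argues against a bias by either. Coverage along transcripts and RNA quality values were not examined, so degraded RNA stays open. A difference in culture or in batch, which the labels do not give, could be the source and stays open.

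In both derivatives 1432 genes changed alike. With an offset per 15 Mb window the count was 845, or 59.0% of that number, and 736 of the 845 were among the 1432. The 59.0% lies between the bounds set for and against shifts of windows, so that this cause stays open. The medians of the 19 autosomes correlated between the derivatives with r = 0.847. Both sets of medians were taken against the same 3 Gcontrol libraries, which can raise r by themselves, so this value decides nothing on descent. Both derivatives may descend from cells that already differed from Gcontrol, which cannot be told apart from an effect of TIM-3 loss here, since no derivative without the edit was sequenced. The 3 Gcontrol libraries shared by both comparisons keep this open too.

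Other groupings of the libraries were fitted. Of the 10 splits of the 6 libraries, too few for a share under 0.05, the real one called 2740, 2109 and 526 genes for G1C7, G2C9 and G1C7 against G2C9; in each case 1 split reached that number and the highest other called 0. For gene lists the real values were 5, 10 and 7 and the highest others 19, 17 and 16, with 9, 4 and 5 of the 10 splits at or above the real value. Among 100 splits of the 9 libraries, the real one included, only the real one reached its own numbers. These were 3124 genes for the mean of both derivatives (highest other 2067), 1432 shared changes (highest other 937) and 15 opposite changes (highest other 1). The real labels thus gave the most genes called, which does not place each library nearest to its own group. In log CPM, G1C7 replicate 2 correlated at 0.974 with G2C9 replicate 3, and at 0.965 and 0.966 with G1C7 replicates 1 and 3. Chance differences between lines or cultures are not excluded by the splits, since each group is 1 line and separate cultures are not given. The split with 2067 genes kept the 3 Gcontrol libraries together and mixed the derivatives. For lists called for the mean of both derivatives, 92 of 100 splits gave 5 or more, up to 17, so that chance is not excluded.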

How the results depend on the processing

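Leaving out both libraries that stood apart, halved counts, limma-voom with quality weights and the offsets were chosen after the data were seen. Counts of called genes stayed within 1.5 times their value under RLE and upper-quartile normalization, under both filters and with halved counts. Fits of the compared groups alone called 3212 genes in G2C9, 80 between the derivatives and 2483 in G1C7, the last within 1.5 times. Fewer libraries set the spread in these fits. Between the derivatives it was set without the Gcontrol libraries, which lay close together. DESeq2 called 1105 genes between the derivatives and 30 in opposite directions, and limma-voom 23 in opposite directions. The cause was not tested. In the simulated counts, 42 of 176 DESeq2 calls between the derivatives were false, against 4 of 113 with edgeR. With the replicate number as a block, 1532, 1114, 1971 and 164 genes were called for G1C7, G2C9, the mean and G1C7 against G2C9, with 706 shared and 5 opposite; the block takes up degrees of freedom, and the numbers do not pair the libraries (correlations of deviations by number 0.409, -0.511 and -0.557). At 2-fold or more, the counts were 988, 841, 1035 and 241, with 522 shared and 5 opposite, since the threshold is stricter.

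Without both libraries that stood apart, 8581, 8383, 9252 and 4320 genes were called, with 6070 shared and 340 opposite, and 14 lists in G1C7 and 13 for the mean. Quality weights gave 8880, 8244, 9375 and 3913, with 6041 shared and 297 opposite. Both settings lower the weight of these libraries, whose spread enters every test. With the 15 Mb window offset, 845 genes were shared, 736 of them among the 1432.

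With one library left out, genes called ranged from 1181 to 4133 in G1C7, 878 to 4113 in G2C9, 1318 to 4986 for the mean and 186 to 1286 between the derivatives. Shared genes ranged from 558 to 2478 and opposite genes from 2 to 45. Lists ranged from 3 to 8, 6 to 13, 4 to 8 and 5 to 9. The highest counts came without G1C7 replicate 2, except for lists in G2C9, highest without G2C9 replicate 3; the cause was not tested. Camera with an estimated correlation called 0 lists in G1C7, 0 in G2C9, 0 for the mean and 0 between the derivatives, and fry called 11 in G1C7, 7 in G2C9, 14 for the mean and 4 between the derivatives; fry asks another question, whether list members change in one direction, without regard to other genes. For changes in any direction fry called 22, 23, 22 and 16 of the 35 lists.

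For Havcr2, the log2 fold change ranged from -1.03 to -0.06 in G1C7, -1.01 to -0.73 in G2C9, -0.94 to -0.45 for the mean and -0.18 to 0.80 between the derivatives with one library left out. In G2C9 it passed the test without both libraries that stood apart (-0.75, adjusted p = 0.0293, between 0.0293 and 0.672 over its alternatives) and without G1C7 replicate 2 (adjusted p = 0.0323). Between the derivatives it reversed under limma-voom (-0.29, adjusted p = 0.921) and without G1C7 replicate 3 (-0.18); the cause was not tested. Of 187 called results of named genes, 124 were called in each of 13 fits (RLE, DESeq2, limma-voom, the block and each library left out), and none reversed. Hmgb1 in G1C7, not called at 0.104, stood at 0.273 without G1C7 replicate 2 and reversed without G1C7 replicate 3 (-0.0186); the cause was not tested. The block kept 144, limma-voom 181, and leaving out one library between 134 and 186. Fits of the compared groups alone give no value for the mean or the shared genes. Depth limits genes near the floor of 3 read pairs, and Havcr2 in G1C7 replicate 2, with 6 reads, lies there. Havcr2 was not tested apart from the lower median of its stretch of chromosome 11.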

Other observations

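The tests of Y loss and of silent neighbours at 0.5 CPM were chosen after the result was seen. Of 19 tested targets and members of the TGF-beta and BMP pathways, 4 rose and 6 fell in G1C7 (6 and 9 adjusted over the list alone) and 4 rose and 5 fell in G2C9 (4 and 8). Camera did not call this list (adjusted p = 0.23 and 0.20; adjusted p = 0.795 and 0.781 with an estimated correlation). Gli2, a transcription factor of the Hedgehog pathway, fell from 1.98 ± 0.41 CPM to 0.0611 ± 0.0417 in G1C7 and had 0 reads in G2C9. Smad6, an inhibitor of BMP signalling, fell from 15.2 ± 0.615 to 7.33 ± 0.418 CPM in G2C9, and Grem1, a BMP antagonist, rose from 913 ± 6.11 to 1682 ± 253 CPM. Ltbp1, which binds latent TGF-beta, rose by 1.04 ± 0.12 in G1C7, and Ltbp2 fell by 1.26 ± 0.16. The tested genes around Ltbp1, on chromosome 17 at 75 to 90 Mb, had a median 0.42 above that of all genes in G1C7. The chemokine Ccl7 fell by 1.73 ± 0.16 in G1C7 and Cxcl16 by 1.96 ± 0.29 in G2C9. Flt1, a VEGF receptor, fell by 1.95 ± 0.24 in G2C9, and Cdh5, an adhesion molecule of endothelium, rose by 2.28 ± 0.24.

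Hedgehog genes as a list did not pass camera in G1C7 (0 of 9 higher and 3 lower, 0 and 3 adjusted over the list alone, adjusted p = 0.0940; adjusted p = 0.767 with an estimated correlation). The 17 hypoxia genes had none called, with medians of 0.51 in G1C7 and 0.29 in G2C9. By library the hypoxia medians were -0.06, 1.24 and -0.11 in G1C7 and 0.02, 0.04 and 0.80 in G2C9. Genes of S phase had medians of 0.07 and 0.06, and those of mitosis -0.02 and 0.03, with 0 and 2, and 1 and 1, of 28 called. Libraries went opposite ways: the S phase medians were 0.21, -0.39 and 0.27 in G1C7 and 0.21, 0.23 and -0.19 in G2C9, and those of mitosis 0.06, -0.29 and 0.06, and 0.12, 0.15 and -0.26, lower in the 2 libraries that stood apart. Camera called none of the hypoxia, S phase and mitosis lists in either derivative (adjusted p of 0.206 or more, and of 0.986 or more with an estimated correlation).

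Il6, Saa3 and Lcn2 were high and Inpp4b low in the 2 libraries that stood apart; these 4 genes were chosen after their values were seen and not tested. Il6 stood at 51.6 CPM in G1C7 replicate 2 (3.01 and 3.32 in the others) and 244 in G2C9 replicate 3 (15.5 and 16.1). Saa3 stood at 596 (39.5 and 41.0) and 1944 (132 and 134), and Lcn2 at 333 (36.4 and 37.4) and 952 (97.5 and 98.5). Inpp4b stood at 3.01 (17.0 and 13.8) and 3.12 (15.5 and 15.9).

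The 15 genes changed in opposite directions included Tmem144 (-2.25 in G1C7 and 1.77 in G2C9), Miga1 (-3.12 and 1.57), Fndc4 (0.97 and -2.48), Tgfb1i1 (0.53 and -1.14) and Ezr (0.31 and -0.92). This count was 45 without G1C7 replicate 2, 32 without G2C9 replicate 3, 8 without G1C7 replicate 3 or G2C9 replicate 1, and 2, 4 and 2 without Gcontrol replicates 1, 2 and 3. It was not made with an offset per chromosome or window. The opposite changes were thus not tested apart from the shifts of chromosomes 3 and 17 between the derivatives (-0.26 and 0.27).

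Of 7 Y-linked genes with 10 or more reads in Gcontrol, 6 had 0 reads in G2C9. Gm47283 (Y, 90784738 to 90816465) had 1996 there, 3088 in Gcontrol and 3465 in G1C7. Loss of the Y chromosome may be the cause. A value above 20 reads had been set as evidence against it, which was wrong: this gene lies at the end of Y that X shares, so its 1996 reads can come from X. The explanation stays open.

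With Y left out, genes at 2 CPM or more in Gcontrol and under 0.1 CPM in every library of a derivative numbered 35 in G1C7 and 28 in G2C9, 19 of them in both. The converse count, of genes silent in Gcontrol, was 1 for each. Of neighbouring pairs with such a gene, 0% held 2, a value that had been set as evidence against loss of stretches of DNA. That bound was wrong, since neighbours under 2 CPM could not count. From 0.5 CPM in Gcontrol, 114 and 117 genes were silent and 7 and 6 neighbouring pairs held 2, where random draws gave up to 5. In a run on chromosome 12, chosen after its values were seen (26300964 to 27342574), Rnf144a, Rsad2, Cmpk2 and Sox11 had 278, 232, 164 and 521 reads in Gcontrol, 2, 2, 2 and 0 in G1C7, and 0, 0, 2 and 0 in G2C9. Loss of stretches of DNA may be the cause for such pairs, and stays open, as does silencing; DNA was not measured. Rsad2 and Cmpk2 belong to the type I interferon list, so their fall need not be part of an interferon change.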
